A study of Saccharomyces cerevisiae with 46 samples.

How the data were processed

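Genomic DNA from overnight yeast cultures was made into tagmentation libraries and sequenced on an Illumina instrument as paired-end reads, per the labels. The deposited values were log2 copy ratios, 1 per bin of 1 kb and sample, in the output format of GATK's copy-number tools, per the file headers. Trimmomatic 0.39, BWA 0.7.17, Picard 2.27.1 and GATK were named per the submitters' processing notes, which gave no GATK version, order or settings. Whether duplicate reads were removed, bins corrected for GC content or a panel of normal samples used was not given in the sources used here. The contig names and lengths in the file headers are those of the R64 assembly of S288C, and the gene table used for names and positions is of the same assembly. W303 differs from S288C in places, so a bin can be under- or over-covered in all samples without a change of copy number.

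Each sample had 12165 bins, of which 86 were mitochondrial. Within each sample the ratio of every covered bin to the median bin was a whole number of reads divided by the median number of reads (100% of values within a tolerance of 0.01 reads), so the read counts could be recovered. This also showed that the values were scaled by the sample's own median bin alone. Recovered totals were 1961866 to 3770032 reads per sample, and 4.92% to 17.2% of them were mitochondrial. The median bin held 130 to 292 reads and the spread between bins within a sample was 0.117 to 0.158 (SD, log2). Nuclear bins without reads numbered 258 to 288 per sample and stood at a floor of -29.9. Single-bin tests gave an empty bin 0.5 reads. Reads without molecular identifiers are not independent molecules, so errors over bins cover counting and bin-to-bin spread within 1 library only.

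The level of a chromosome was the median log2 copy ratio of its bins minus the sample baseline, itself the median over the 16 nuclear chromosome medians. A level at or above 0.3 was called a gain and one at or below -0.3 a loss. Ploidy was not given in the sources used here, so levels are relative and an even change of all chromosomes would not be seen. Level differences between the states were tested with paired sign-flip permutation tests over the 20 lines (100000 resamples, two-sided), called gains with exact McNemar tests, and both were adjusted by Benjamini-Hochberg over 16 chromosomes. Unequal gain was tested by shuffling the gains of each line over the chromosomes, and shared gains by shuffling evolved samples over lines. Pairs of chromosomes gained in at least 4 lines each were tested with Fisher's exact test, and relations to length with permutation tests of Pearson's r and Spearman's rho. The evolved_Bub3 samples were compared with evolved samples of the same 3 lines by exact sign-flip tests. The wildtype, with 1 sample per state, was not tested.

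Single bins were compared with limma on log2 ratios minus the median of their chromosome in that sample, with the line as block, over 11810 nuclear bins. The 269 bins without reads in over 50% of the samples were left out. Segments were found by recursive binary splitting with a minimum of 20 bins and a step of at least 0.3, after values had been limited to between -2 and 3. A mitochondrial bin counted as covered above -2. The mitochondrial, ribosomal DNA and CUP1 levels were the log2 of the mean copy ratio of their bins, with empty bins at 0, minus the sample baseline. Loci such as BUB3 were the mean of the bins they overlap, minus the median of their chromosome. The means given for the genes of the lists are relative to the sample baseline. The lists, tests, thresholds, the rule for names and 101 of the 134 alternative settings were fixed before the data were examined, and the other 33 alternatives were added afterwards. By that rule the text names chromosomes that passed a correction or were gained in at least 4 of 20 lines in a state, BUB3, list members on the 5 chromosomes with most gains, the 10 called bins with the largest change, and all fixed repeat loci. Other items named, such as the URA3 gene and the stretches of mitochondrial DNA, were chosen after their values were seen. All 130 listed genes matched the gene table.

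Samples were paired by the line code shared between titles. As a check of the pairing, the deviations of bins from their group means were correlated between the states of a line over 11607 bins. The correlations were -0.02 to 0.04 (median 0.01), with 0 of 20 lines above 0.1, so these deviations gave no sign of the pairing, which was taken from the labels. No pair of samples within a group agreed within sampling noise: the chi-square per degree of freedom between the nuclear read counts of 2 samples was 1.68 to 2.49 in the non-evolved, 1.67 to 2.50 in the evolved and 1.83 to 1.96 in the evolved_Bub3 group, and each sample was counted separately. The labels do not say how the lines relate to each other or whether lines that share a letter have a common origin. The p-values therefore measure the spread between these lines, and those of limma also draw on the spread of other bins.

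The steps were tested on simulated data. With 200 bins changed among 11810 bins of the comparison of states, all 50 bins at each of -1, -0.3, 0.3 and 1 were recovered with the right sign, and 12 of 11610 unchanged bins were called. A chromosome gained in a share of 0.5 or 1 of the cells was called in 200 of 200 simulations, and one gained in a share of 0.2 in 0 of 200. The simulated cells held 1 copy before the gain, and cells with more copies, in which a gain changes the level less, were not simulated. For differences between 20 lines the sign-flip test passed 0.05 in 7 of 100 simulations without a shift and in 99 of 100 with a shift of 0.5.

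Alternatives covered the call threshold (0.2 and 0.5), the mean of bins, no baseline, bins within 20 kb of chromosome ends left out, unpaired tests, the 7 letters as units, another distance between profiles, gene number in place of length, each evolved_Bub3 line left out, other filters of bins and segments, lines A1 and A4 left out, and random gains that keep the number of gains of each line and of each chromosome (100000 matrices, from repeated trades of gains between 2 lines). Arms were not compared at the centromere because the gene table used here has no centromere positions, and the 2-micron plasmid is not among the contigs analysed here. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.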

Results

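The study asked how gains of particular chromosomes relate to the loss of Bub3, a component of the spindle assembly checkpoint, which delays chromosome separation until the chromosomes are attached to the spindle. Genomic DNA of budding yeast cultures of the W303 background was sequenced, and read depth was expressed as a log2 copy ratio in 12165 bins of 1 kb. The series held 46 samples. A set of 20 lines, each named by a letter and a digit, was sampled in a non-evolved and in an evolved state. For 3 of these lines, C2, E3 and G4, there was a further sample called evolved_Bub3. A wildtype strain, LY1, had 1 sample in each of these 3 states and therefore no replicates. The labels gave neither the genotype of the lines, nor the ploidy, nor what distinguished evolved_Bub3 samples from evolved ones. The reads recovered from the ratios amounted to 1961866 to 3770032 per sample, with a median of 130 to 292 reads per bin.

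The BUB3 gene was under-covered in many of the lines and over-covered in every evolved_Bub3 sample. BUB3 (YOR026W, chromosome XV 379781 to 380806 in R64) overlaps 2 bins, and their mean log2 level relative to chromosome XV ranged from -1.46 to 0.08 in the non-evolved lines (median -1.04) and from -1.44 to 0.11 in the evolved lines (median -1.07). The level lay under -1 in 10 of 20 non-evolved and 11 of 20 evolved samples. In the wildtype it was 0.01 in the non-evolved and -0.03 in the evolved state. In the evolved_Bub3 samples it was 0.76 in C2, 1.42 in E3, 1.34 in G4 and 1.19 in the wildtype. BUB3 fills only part of its 2 bins, so these levels are not copy numbers of the gene itself, and no genotype was read from them.

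**Figure D1:**
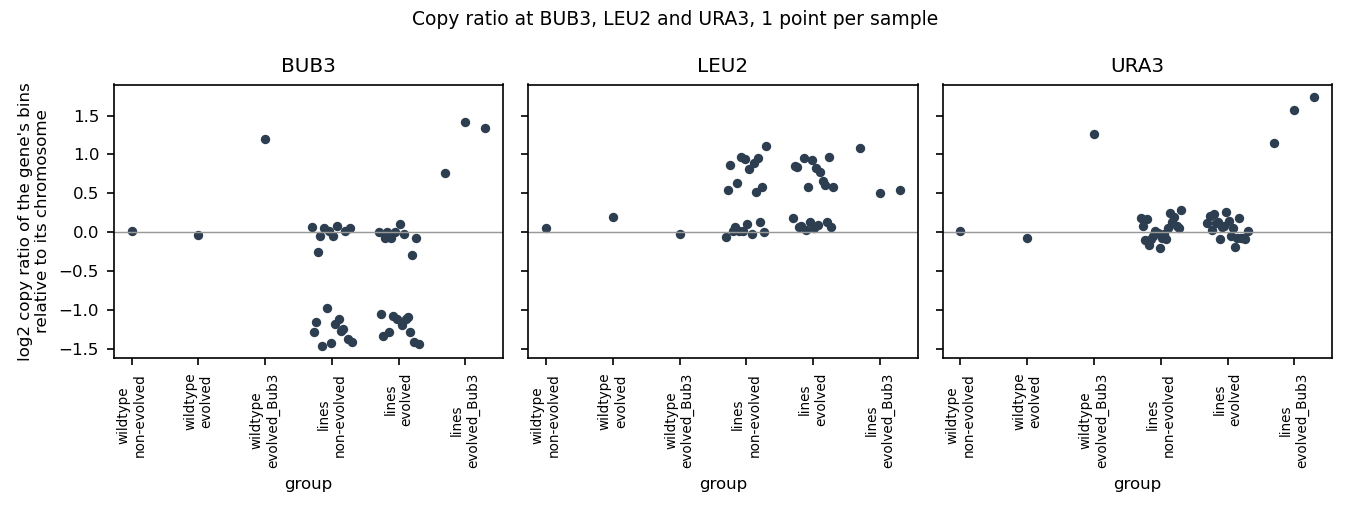
Log2 copy ratio of the bins of BUB3, LEU2 and URA3 relative to the chromosome each lies on (vertical axis, log2), with 1 point per sample and the groups along the horizontal axis. BUB3 lay between -1.46 and 0.11 in the lines and between 0.76 and 1.42 in the 4 evolved_Bub3 samples, where URA3 lay between 1.15 and 1.74.

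Whole-chromosome gains were common in both states of the lines, and no chromosome was lost in any sample. Among the non-evolved samples 13 of 20 carried at least 1 gained chromosome, with 23 gains in all, and the evolved samples carried 25 gains, again in 13 of 20. The mean number of gains per line was 1.15 ± 0.93 (SD, n = 20) before and 1.25 ± 1.12 (SD, n = 20) after evolution, with at most 2 and 3 in a line. The same 7 lines, B2, C1, C3, D1, D3, F3 and G1, had no gain in either state. Gains were not spread evenly over the levels of BUB3 relative to XV. All 11 lines with BUB3 at -0.97 or below carried gains in both states. Among the lines with BUB3 at -0.29 or above, only A1 and A4 carried gains, of XI and XII alone. The difference of 0.1 gains per line (95% bootstrap interval -0.2 to 0.4) was within the spread between lines (p = 0.754, two-sided paired sign-flip permutation test, 100000 resamples), with more gains in 6 lines, fewer in 4 and equal numbers in 10. A gain was a chromosome level at or above 0.3 on the log2 scale, relative to the sample's own baseline.

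Most gains lay close to a doubling over the baseline. The median level of a gained chromosome was 0.90 in the non-evolved samples (range 0.71 to 1.0) and 0.92 in the evolved samples (range 0.37 to 1.29), where 1 on the log2 scale is a doubling. In each state 20 gains lay at 0.8 or above, which left 3 and 5 gains between 0.3 and 0.8. Chromosome VIII had such intermediate levels in A3 evolved (0.69), C4 evolved (0.68), and D4 in both the non-evolved (0.71) and the evolved state (0.63). The lowest called gains were chromosome III of D4 evolved, at 0.37, and chromosome X of B3 evolved, at 0.39. The highest level was that of chromosome I in B3 evolved, at 1.29. The standard error of a chromosome level over its bins was at most 0.02 in the samples of the lines, far below these differences, and it covers the spread between bins of 1 library only. A further 9 non-evolved and 14 evolved levels lay between 0.1 and 0.3, under the threshold.

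**Figure D2:**
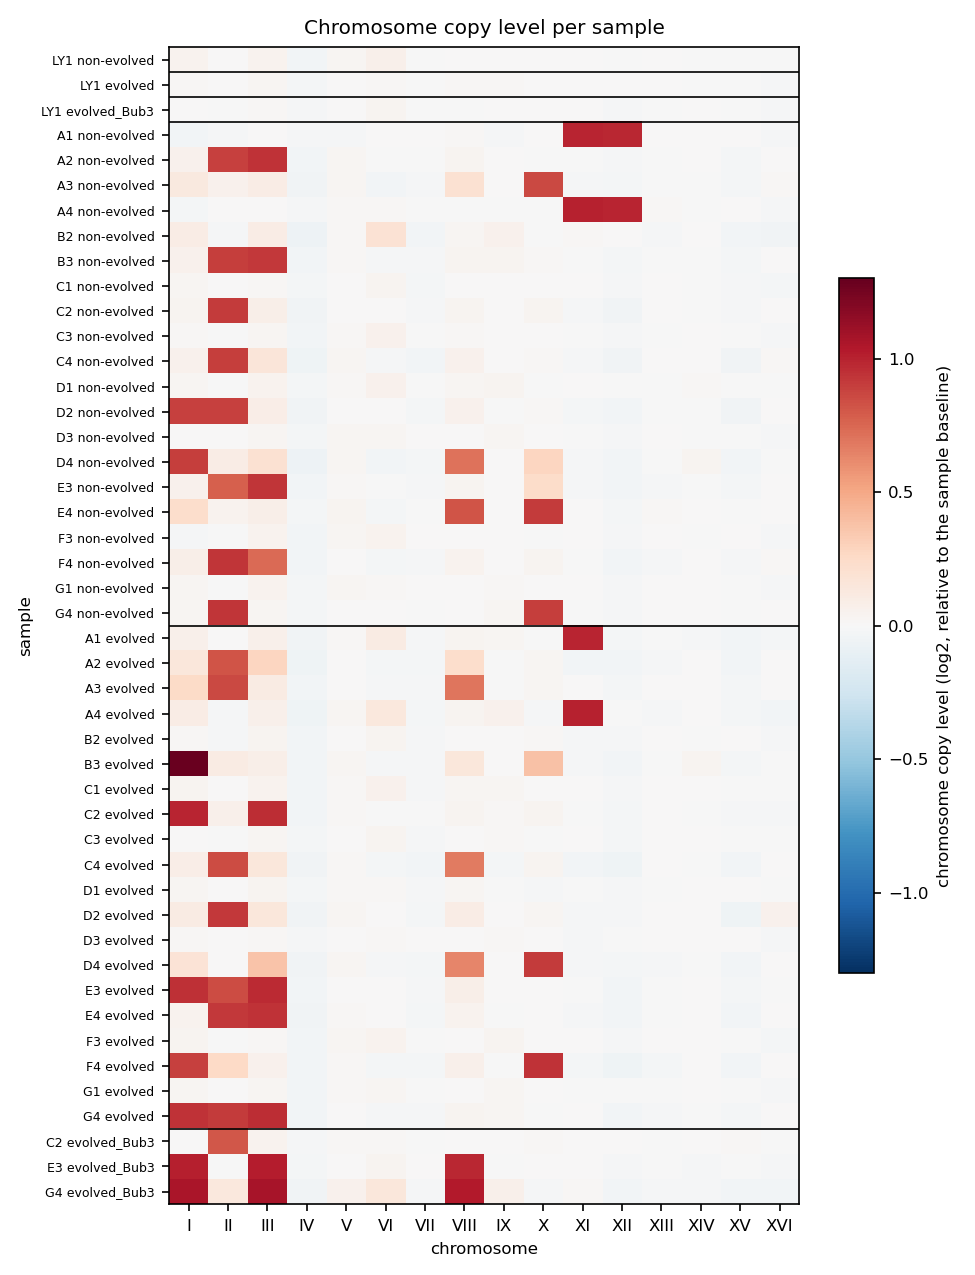
Heatmap of the log2 copy level of each of the 16 nuclear chromosomes (horizontal axis) relative to the sample baseline in each of the 46 samples (vertical axis, grouped by state, with the wildtype LY1 at the top). Red cells are gains, up to 1.29 for chromosome I of B3 evolved, and the wildtype samples lay between -0.03 and 0.06.

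Gains fell on a small set of chromosomes, and chromosome II was gained most often. It was gained in 8 of 20 non-evolved and 7 of 20 evolved samples, chromosome III in 4 and 5, and chromosome I in 2 and 5. Chromosome X was gained in 3 samples of each state, or in 5 non-evolved and 3 evolved samples at a threshold of 0.2. VIII was gained in 2 and 3, XI in 2 and 2, and XII in 2 non-evolved samples alone. The other 9 chromosomes were gained in no line in either state. When the gains of each line were shuffled over the 16 chromosomes, the variance over chromosomes of the number of lines with a gain (4.50 non-evolved, 5.12 evolved) was higher than almost any shuffle gave (p = 2e-05 and 1e-05, the latter the smallest the 100000 resamples can give, one-sided permutation test). Shuffling put 1.44 and 1.56 lines on each chromosome on average. Chromosome II alone passed the correction over 16 chromosomes (adjusted p = 0.00048 non-evolved, gained in 8 lines, and 0.00448 evolved, gained in 7 lines). In the evolved samples I and III, each gained in 5 lines, had an adjusted p of 0.0691 and did not pass. Both passed at a threshold of 0.2 (gained in 6 lines each, adjusted p = 0.0246) and, a choice made after the data were seen, without A1 and A4 (adjusted p = 0.0421).

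**Figure D3:**
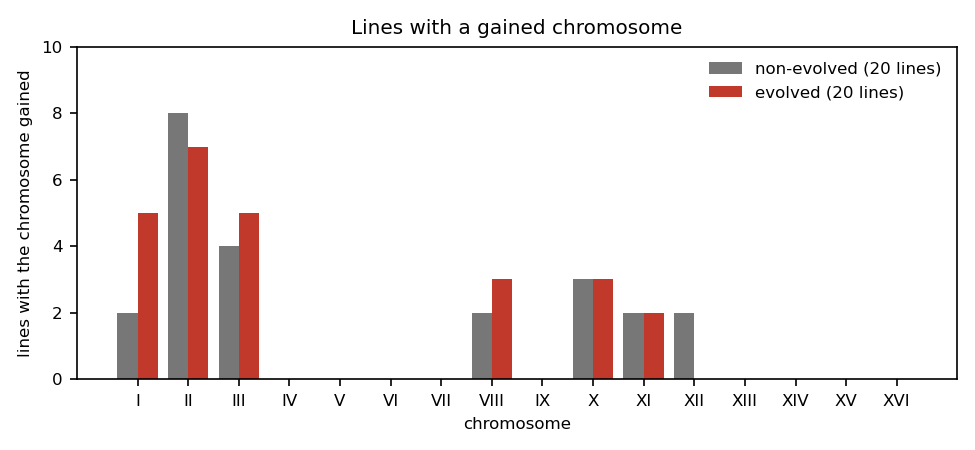
Number of lines (vertical axis, of 20 per state) in which each chromosome (horizontal axis) was gained, with grey bars for non-evolved and red bars for evolved samples. Chromosome II reached 8 and 7 lines, and 9 chromosomes were gained in no line.

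Chromosome levels were then compared between the states of each line. Chromosome I had a mean level of 0.13 ± 0.27 (SD, n = 20) in the non-evolved and 0.31 ± 0.43 in the evolved samples, and it was higher in the evolved sample of 14 lines. Its difference of 0.18 ± 0.53 did not pass the correction (adjusted p = 0.632, raw p = 0.132). Chromosome II had 0.36 ± 0.44 and 0.33 ± 0.42, a difference of -0.04 ± 0.41 with 7 lines higher (adjusted p = 0.973), and chromosome III had 0.23 ± 0.34 and 0.27 ± 0.37, a difference of 0.04 ± 0.46 with 10 lines higher (adjusted p = 0.973). The lowest raw p, 0.0436, belonged to chromosome XII (-0.10 ± 0.31, higher in 8 lines, adjusted p = 0.632), which was gained in A1 and A4 non-evolved and in no evolved sample. The two-sided paired sign-flip permutation test called 0 of 16 chromosomes after Benjamini-Hochberg adjustment, and 1 had an unadjusted p under 0.05. The exact McNemar test on the called gains also called 0 of 16. Its lowest p was 0.453 (adjusted p = 1), for chromosome I, which was newly gained in 5 lines and no longer gained in 2, and 0 of the 16 had an unadjusted p under 0.05. Libraries were numbered by state, so library order and state cannot be told apart.

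Although the number of gains was similar, the chromosomes gained in a line mostly differed between its states. Of the gains, 9 were present in both states of the same line, 14 were present in the non-evolved sample alone and 16 in the evolved sample alone. None of the 13 lines with gains had the same set in both states, and 5 of them shared no gained chromosome between the states. At the threshold of 0.3, chromosome II was gained in both states of 5 lines, XI of 2, and III and VIII of 1 each. I and X were gained in both states of 0 lines. In B3, for example, gains of II and III (0.89 and 0.92) in the non-evolved sample stood against gains of I and X (1.29 and 0.39) in the evolved one, and in E4 gains of VIII and X (0.81 and 0.91) stood against gains of II and III (0.92 and 0.94). A1 and A4 both carried XI and XII before evolution (0.98 to 1.0) and XI alone after it (0.99 and 1.0). The 9 shared gains exceeded the 5.25 expected when evolved samples were reassigned among the lines (p = 0.0362, one-sided permutation test). At a threshold of 0.2, 12 shared gains stood against 6.65 (p = 0.00918, the same test). There III of A2 evolved (0.28), II of F4 evolved (0.25) and X of D4 non-evolved (0.28) also counted as gains. The reassignment mixed the 7 lines without a gain in either state with the other 13. When the number of gains of each line and of each chromosome was kept within each state, a choice made after the data were seen, 8.03 shared gains were expected (p = 0.387, one-sided permutation test). The excess over 5.25 was therefore not shown beyond which lines and which chromosomes had gains. Without A1 and A4, also left out after the data were seen, 7 shared gains stood against 5.61 (p = 0.295) and, with those numbers kept, against 9.23 (p = 0.955).

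Of the 4 pairs of chromosomes tested, each gained in at least 4 lines, none was gained together past the correction. XI and XII were each gained in 2 non-evolved samples, A1 and A4 for both, and this pair was not tested. All 4 non-evolved samples with a gain of III (A2, B3, E3 and F4) also carried II, which was gained without III in 4 others, while 12 lines had neither (p = 0.0144, adjusted p = 0.0578 over 4 pairs of chromosomes, two-sided Fisher's exact test). This test counts the 7 lines without any gain among the 12. With the number of gains of each line and chromosome kept, p was 0.0229 (adjusted p = 0.0916, two-sided permutation test, chosen after the data were seen), with 1.88 such samples expected. In the evolved samples I and III were gained together in 3 lines, C2, E3 and G4, each chromosome alone in 2, and neither in 13 (p = 0.0726, adjusted p = 0.145, Fisher's exact test), and with those numbers kept the adjusted p was 0.229. The evolved pairs I with II (2 lines with both, adjusted p = 1) and II with III (3 lines with both, adjusted p = 0.386) had larger p-values in the same exact test.

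Neither chromosome length nor the letter of a line was related to the gains past the threshold. Across the 16 chromosomes, which are not independent replicates, the number of lines with a gain had a Pearson r of -0.19 with length in the non-evolved samples (permutation p = 0.468, adjusted p = 0.468) and a Spearman rho of -0.31 (p = 0.239, adjusted p = 0.319). In the evolved samples r was -0.42 (p = 0.11, adjusted p = 0.219) and rho -0.47 (p = 0.0708, adjusted p = 0.219), all from two-sided permutation tests adjusted over these 4 relations. Leaving out IV and I, the chromosomes farthest from the median length, gave an r of -0.10 and -0.27. The mean Euclidean distance between the chromosome profiles of lines that share a letter, minus that between other lines, was -0.02 in the non-evolved samples (p = 0.827, two-sided permutation test) and -0.04 in the evolved samples (p = 0.71).

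The 3 lines with an evolved_Bub3 sample showed different chromosomes gained there than in the evolved sample of the same line. They were the 3 lines whose evolved samples carried both I and III. In C2, chromosome I stood at 0.99 in the evolved and 0.00 in the evolved_Bub3 sample, and III at 0.96 and 0.04, whereas II stood at 0.06 and 0.81. The non-evolved C2 sample had II at 0.91. In E3, II stood at 0.85 in the evolved and 0.00 in the evolved_Bub3 sample and VIII at 0.07 and 0.98, while I and III remained gained at 1.01 and 1.02. In G4, II stood at 0.91 and 0.13 and VIII at 0.04 and 1.03, while I and III remained gained at 1.06 and 1.07. A chromosome changed its call 7 times over these 3 lines.

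The mean evolved_Bub3 minus evolved difference was 0.62 ± 0.57 (SD, n = 3) for VIII and -0.30 ± 0.90 for II (p = 0.5 for both, exact two-sided sign-flip permutation test). It was -0.27 ± 0.63 for I and -0.25 ± 0.58 for III (p = 1 for both, the same exact test). With 3 lines the smallest p this test allows is 0.25, so it could not pass at 0.05. The signs for I and III rested on C2 and turned positive without it, to 0.0933 and 0.0802. The wildtype had no gain in any state, with chromosome levels of -0.03 to 0.06 in the non-evolved sample, -0.03 to 0.02 in the evolved one and -0.02 to 0.03 in the evolved_Bub3 one.

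Several genes of the spindle and the checkpoint lie on the chromosomes that were gained; the levels given are means over the non-evolved and then over the evolved samples. Of 130 genes in 9 lists fixed beforehand, 22 lie on II, III, I, X or VIII, the chromosomes with most gains. In that order these hold 416, 168, 94, 365 and 293 of the 6002 nuclear protein-coding genes. The 22 listed genes are therefore no excess over the share of all genes on these chromosomes. The checkpoint list (6 genes) has MAD2 and MAD3 there, both on X, with mean levels of 0.13 ± 0.34 (SD, n = 20) and 0.14 ± 0.34 in the non-evolved and 0.11 ± 0.32 and 0.11 ± 0.28 in the evolved samples. Of the chromosomal passenger and shugoshin list (5 genes), which acts in correcting attachments to the spindle, SLI15 on II (0.29 and 0.26), BIR1 on X (0.15 and 0.10) and NBL1 on VIII (0.19 and 0.26) lie there. The anaphase-promoting complex list (18 genes), of the ubiquitin ligase that triggers chromosome separation, has CDC23 on VIII (0.13 and 0.18) and CDC27 on II (0.35 and 0.35). The phosphatase list (11 genes) has TPD3, a regulatory subunit of protein phosphatase 2A, on I (0.07 and 0.28).

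The kinetochore list (40 genes) has 7 members on these chromosomes. They are MTW1 on I (mean level 0.14 in the non-evolved and 0.31 in the evolved samples), AME1, IML3 and DAD3 on II (0.35, 0.42 and 0.46, then 0.31, 0.33 and 0.37), and NNF1, MCM22 and CBF1 on X (0.23, 0.19 and 0.18, then 0.17, 0.08 and 0.17). The tubulin and motor list (20 genes) has KIP1 and STU1 on II (0.33 and 0.29, then 0.30 and 0.27) and BIK1 on III (0.27, then 0.32). The cohesin list (9 genes) has SMC3 on X (0.13 and 0.07). The proteotoxic stress list (13 genes) has the chaperone gene SSA1 on I (-0.32 and -0.10), whose sequence is close to that of SSA2 so that reads may be divided between them. The strain marker list (8 genes) has LEU2 on III (0.68 and 0.74) and LYS2 on II (0.40 and 0.36). LEU2 stood at 0.5 or above in 11 lines of each state, whereas III was gained in 4 and 5, so its level is not that of III alone.

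No list passed the comparison with random genes. Members of the chromosomal passenger and shugoshin list were on a gained chromosome in 13% of lines in each state, against 6.27% and 5.67% for random lists of that size, at percentiles 90.0 and 91.5 of 10000 random lists (adjusted share 0.498 and 0.878). The checkpoint list stood at 5.0% in both states and the kinetochore list at 6.63% and 5.88%. The anaphase-promoting complex list stood at 4.44% and 3.33%, the phosphatases at 1.82% and 3.18%, and tubulin and motors at 5.50% and 4.75%. Cohesin stood at 1.67% in both, proteotoxic stress at 2.31% and 1.92%, and the strain markers at 8.75% and 7.50%. Of the 9 lists, 0 passed an adjusted two-sided share of 0.05 in either state. Gene by gene, the paired sign-flip permutation test of evolved against non-evolved levels called 0 of 130 genes over all genes tested (lowest adjusted p = 0.736) and 0 adjusted over the list alone (lowest adjusted p = 0.173), and 6 genes had an unadjusted p under 0.05.

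Most of the mitochondrial genome had few or no reads in 5 of 20 evolved samples, and in 0 of 20 non-evolved ones. The mitochondrial genome, present in many copies per cell, averaged a log2 level of 4.14 ± 0.36 (SD, n = 20) in the non-evolved and 3.93 ± 0.37 in the evolved samples, or 17.6-fold and 15.3-fold over the baseline. In D1 and D3 evolved the only covered stretch was 41001 to 51000, which holds COB, BI4, OLI1 and VAR1, at a mean of 118-fold and 107-fold over the baseline. In C3 evolved it was 34001 to 36000, at a mean of 18.9-fold, and 47001 to 51000 with VAR1, at 207-fold. B3 evolved kept 1 to 5000 and 69001 to 85779 with COX2, Q0255 and COX3, at means of 39.8-fold and 57.5-fold. A1 evolved kept 81001 to 84000 at a mean of 212-fold, with single bins from 29.5-fold to 550.2-fold. These samples covered 10, 10, 6, 22 and 3 of the 86 mitochondrial bins, with 5, 64, 42, 40 and 315 reads over all the rest.

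The exact two-sided McNemar test of 5 lines against 0 gave p = 0.0625, the smallest p that 5 lines allow, so it could not pass at 0.05. Of the wildtype and evolved_Bub3 samples, 0 had such a gap. The stretches were noticed in the data and their count was not among the comparisons chosen beforehand. The mean mitochondrial level differed by -0.20 ± 0.54 between states, with 6 lines higher in the evolved sample (p = 0.0694, adjusted p = 0.257, two-sided paired sign-flip permutation test over 4 loci). Much of it came from A1, which stood at 5.03 in the non-evolved and 2.89 in the evolved sample. Without A1, left out after the data were seen, the difference was -0.10 ± 0.29 (p = 0.139, n = 19). With the median of the mitochondrial bins in place of their mean the difference was -3.13 (p = 0.0183), since most mitochondrial bins of those 5 samples held few or no reads and set their medians.

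None of the 4 repeat loci, the mitochondrial genome included, differed between the states past the correction. The ribosomal DNA (XII 451001 to 468000), collapsed in the reference to a few of its many copies and covered in only part of its 17 bins, stood at 2.92 ± 0.39 (SD, n = 20) in the non-evolved and 2.71 ± 0.34 in the evolved samples. Its difference was -0.22 ± 0.59, higher in 7 evolved samples (adjusted p = 0.257, sign-flip permutation test). It rested mostly on A1 (3.98, then 2.13) and A4 (3.68, then 2.06), whose non-evolved samples also had XII gained. The difference was -0.13 (p = 0.256) without A1, -0.05 ± 0.30 (p = 0.511, n = 18) without both, and -0.11 (p = 0.172) relative to chromosome XII, all chosen after the data were seen. The CUP1 array (VIII 212001 to 215000), which holds tandem copies of a copper-binding metallothionein gene, stood at 0.70 ± 0.31 and 0.65 ± 0.30, a difference of -0.04 ± 0.30 with 7 lines higher (adjusted p = 0.703). Relative to chromosome VIII itself, a choice made after the data were seen, the CUP1 difference was -0.0822 (p = 0.0118), and with the median of its bins it was -0.12 (p = 0.121). The bins within 20 kb of chromosome ends stood at -0.09 ± 0.06 and -0.08 ± 0.04 (adjusted p = 0.707, higher in 13 lines by 0.01 on average).

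Within chromosomes, recurrent changes were few. Of 11810 nuclear bins, limma with the line as block called 1, which was lower in the evolved samples, and 564 had an unadjusted p under 0.05. This bin, XV 595001 to 596000, lies in a Ty1 retrotransposon (YOR142W-B and YOR142W-A) and held only 4 to 21 reads per sample. It differed by -0.53 (SE 0.09, adjusted p = 0.0424, lower in 17 of 20 lines). Without the block limma called 0 bins, with 572 at an unadjusted p under 0.05. With low, high and terminal bins left out it called another bin, XII 461001 to 462000 in the ribosomal DNA (RDN37-2, RDN25-2), at -0.32 (adjusted p = 0.00347, lower in 14 lines). The difference of this bin was the same in limma over all bins, where its adjusted p was 0.985. Its SE was 0.11 over all bins and 0.06 with those bins left out.

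Segmentation found no partial gain of a chromosome that set the states apart. It placed 55 breakpoints in 40 of the 46 samples. Of these, 38 separated a higher left end of chromosome I, whose edge lay 23000 to 25000 bp from the end, 15 separated a lower right end of VIII that began at 527001 to 529001, and the other 2 lay on II and IX of B2 non-evolved. When the non-evolved sample of a line was subtracted from its evolved sample, which was done after the data were seen, 0 breakpoints were left, and 0 were left between the evolved_Bub3 and evolved samples of the 3 lines. Simulated steps of 0.3 in a chromosome were found in 4 of 100 cases and steps of 0.58 in 100 of 100, so partial gains near 0.3 would mostly be missed, and sizes between these were not simulated.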

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

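BUB3 and URA3 were over-covered in the wildtype sample called evolved_Bub3, in a strain that no comparison between groups used. BUB3 stood at 1.19 and URA3 at 1.26 relative to their chromosomes, against 0.01 and 0.02 in the non-evolved and -0.03 and -0.07 in the evolved wildtype sample. The same held for the evolved_Bub3 samples of the lines, where BUB3 stood at 0.76 in C2, 1.42 in E3 and 1.34 in G4, and URA3 at 1.15, 1.57 and 1.74. In the other 42 samples BUB3 reached at most 0.11 and URA3 at most 0.29. The labels do not say how evolved_Bub3 samples were made, and no explanation was tested.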

How the results depend on the processing

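Of 134 alternatives over 32 results, 120 kept the direction and the side of the threshold or, for counts, a similar number, and the others are given here. Part of these could not have come out otherwise. With 2 evolved_Bub3 lines left, the smallest p the sign-flip test allows is 0.5. Leaving out A1 and A4 cannot change the numbers of lines with I, II or III gained. The alternatives without A1 or without A1 and A4, with CUP1 relative to VIII and rDNA relative to XII, with numbers of gains kept and with states subtracted before segmentation were chosen after seeing the data. The number of gains per line never differed between states past 0.05 (differences 0 to 0.222 over its alternatives), and 0 chromosomes passed the correction under any alternative of the level or the McNemar test. Chromosome gains stayed unequal under all alternatives run, while 3 chromosomes, I, II and III, in place of II alone passed in the evolved samples at a threshold of 0.2 and without A1 and A4. With the numbers of gains of lines and chromosomes kept, the 9 gains shared between states stood against 8.03 expected (p = 0.387), since lines without gains no longer lower the expectation. Without A1 and A4, which both kept XI, 7 stood against 5.61 (p = 0.295), or against 9.23 with those numbers kept (p = 0.955). With the Jaccard distance between sets of gained chromosomes, lines that share a letter differed more than others, by 0.0153 in the non-evolved and 0.0154 in the evolved samples (p = 0.877 and 0.851, permutation test), and the cause was not tested.

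Leaving out each line in turn moved the evolved_Bub3 minus evolved difference between -0.464 and 0.0933 for I, -0.818 and -0.0173 for II, -0.437 and 0.0802 for III, and 0.436 and 0.951 for VIII, with both positive values for I and III coming without C2. The median of mitochondrial bins gave -3.13 (p = 0.0183), through the mostly empty bins of 5 evolved samples, and CUP1 relative to chromosome VIII gave -0.0822 (p = 0.0118), with the cause not tested. The rDNA difference relative to XII was -0.113 (p = 0.172). Without A1 and A4 the chromosome ends turned to -0.00551 (p = 0.733), as A4 was among the lines higher after evolution. The median of rDNA bins gave no value, since most of those bins held no reads in most samples. The number of breakpoints, 55, was 12 with a step of 0.5, 1 with segments of at least 40 bins, and 0 after subtracting the non-evolved sample, which removes features shared by both states.

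Without the replicate block, that is without pairing by line, limma called 0 bins (lowest adjusted p = 0.751) in place of 1, and the difference in gains kept its value of 0.1 (p = 0.876). The block changed no other call. With low, high and terminal bins left out limma again called 1 bin, but a different one, on XII, whose adjusted p was 0.985 among all bins, while the bin on XV had been left out. The difference of the bin on XII was -0.32 in both fits, and its SE was 0.11 over all bins and 0.06 after the filter. Its call therefore rested on the smaller SE and not on a larger difference. The values of this bin were the same in both fits. The smaller SE came from the set of bins fitted with it, as limma draws the variance of each bin towards theirs. The swaps of states between random lines were run over all bins and did not cover this call. The bin on XV held 4 to 21 reads per sample and that on XII 111 to 489, and the effect of depth on these calls was not tested.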

Other observations

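In this part the tests of a library deposited in duplicate, of carried reads, of a swap and of noise were chosen after the result was seen. The levels of BUB3 in the lines fell into 2 clusters, with a gap between -0.97 and -0.29. Given as non-evolved and then evolved, BUB3 stood at -1.28 and -1.05 in A2, -1.15 and -1.34 in A3, -1.46 and -1.29 in B3, -0.97 and -1.08 in C2, -1.42 and -1.12 in C4, and -1.18 and -1.20 in D2. It stood at -1.12 and -1.12 in D4, -1.28 and -1.09 in E3, -1.25 and -1.29 in E4, -1.38 and -1.41 in F4, and -1.41 and -1.44 in G4. In the other cluster it stood at 0.07 and 0.01 in A1, -0.25 and -0.08 in A4, -0.05 and 0.01 in B2, 0.05 and -0.07 in C1, 0.01 and 0.01 in C3, -0.05 and 0.11 in D1, 0.08 and -0.03 in D3, 0.02 and -0.29 in F3, and 0.05 and -0.07 in G1. Each of the 20 lines was in the same cluster in both states, 11 below the gap and 9 above it. LEU2, a gene of leucine synthesis on III, had 2 clusters as well, with a gap between 0.19 and 0.52 relative to its chromosome. In the same order of states it stood at 0.54 and 0.86 in A2, 0.87 and 0.84 in A3, 0.63 and 0.95 in B3, 0.96 and 0.58 in C2, 0.94 and 0.93 in C4, and 0.82 and 0.83 in D2. It stood at 0.89 and 0.77 in D4, 0.52 and 0.65 in E3, 0.95 and 0.61 in E4, 0.57 and 0.97 in F4, and 1.11 and 0.59 in G4. Below the gap it stood at -0.06 and 0.19 in A1, 0.02 and 0.07 in A4, 0.07 and 0.07 in B2, 0.02 and 0.02 in C1, 0.01 and 0.12 in C3, 0.10 and 0.05 in D1, -0.03 and 0.09 in D3, 0.13 and 0.13 in F3, and 0.01 and 0.07 in G1. The 11 lines above the LEU2 gap were those below the BUB3 gap, in both states, so these 2 loci set no sample apart from its pair by label. All 11 lines below the BUB3 gap carried gains in both states, of I, II, III, VIII or X alone. The 7 lines without a gain in either state, B2, C1, C3, D1, D3, F3 and G1, all lay above it. Of the lines above the gap only A1 and A4 carried gains, of XI and XII. This split was seen in the data and was not tested, since the labels do not give the genotype of these lines.

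The level of the CUP1 array differed widely between samples, and a gain of VIII, on which it lies, enters this level. The array stood at 0.12 and 0.03 in the non-evolved and evolved samples of F3 and at 0.18 and 0.26 in those of F4, relative to the sample baseline. It stood at 2.03 in G4 evolved_Bub3 and 1.58 in E3 evolved_Bub3, both with VIII gained, against 0.67 and 0.53 in the evolved samples of these lines.

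D1 and D3 evolved had retained the same 10 kb of the mitochondrial genome, 41001 to 51000. The chi-square per degree of freedom between their nuclear read counts was 1.68, so the 2 samples do not hold the same reads. It cannot decide whether 1 library was sequenced under both names, since the value that would give was not measured. The value of 1.68 was the second lowest of 190 evolved pairs (1.67 to 2.50, median 1.86). D1 and D3 non-evolved were the lowest of 190 non-evolved pairs, also at 1.68. The rDNA level of both lines was lower in the evolved sample, 2.80 and then 2.25 in D1 and 2.81 and then 2.02 in D3, against at least 2.51 in the evolved samples of the other 16 lines apart from A1 and A4. Levels as low as that of D1 also occurred elsewhere, with 2.20 in A2 non-evolved and 2.13 and 2.06 in A1 and A4 evolved. The level of the retained part in D3 was 90.8% of that in D1. Reads carried from one library into the other would therefore make up most of the receiving library, nuclear reads included. The chi-square of 1.68 cannot decide this either, so carried reads stay open. The retained part was not in excess beforehand (0.14 and 0.12 in D1 and D3 non-evolved, log2 over the other mitochondrial bins, within the 0.07 to 0.20 of the other 18 lines). A single culture sampled under both names may have given the pair and stays open: 0 of 8 nuclear bins that differed by over 0.6 between D1 and D3 non-evolved kept the difference, but differences in single bins of the 2 samples may be noise. Cells carried over in such a large share would equal a single culture and stay open with it. Independent losses with the same endpoints stay open as well and were not tested.

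A1 and A4 non-evolved shared gains of XI and XII, which no other line had, the highest mitochondrial and rDNA levels of the non-evolved lines, and a higher level over a Ty3 retrotransposon, YGR109W-B (VII 707610 to 712254). Over 4 of its bins it stood at -0.09 and -0.28 in these samples and at -1.12 and -1.32 in their evolved samples, against -1.35 to -0.92 in the other 44 samples. The mitochondrial level was 5.03 in A1 and 4.90 in A4 non-evolved, against at most 4.41 in the other 18 non-evolved lines, and that of the rDNA, which lies on the gained XII, was 3.98 and 3.68 against at most 3.19. The chi-square per degree of freedom between them was 1.80, so they do not hold the same reads. It lay within that of other non-evolved pairs (1.68 to 2.49). It cannot decide whether 1 library was sequenced under both names, since the value that would give was not measured. A swap of these samples with those of a line on the other side of the BUB3 gap is argued against by BUB3, since 0 of 20 lines had their states on different sides of it. A swap with another of the 9 lines above the gap was not excluded, although 2 values go against it. XI stood at 0.99 in A1 and 1.0 in A4 in both states and at most at 0.02 in the 42 samples of other lines, but gains often differed between the states of a line. The bin of the HMR cassette lay above its gap of -0.30 to -0.07 in both states of A1 and A4. It lay below the gap in both states of B2, C1, F3 and G1, but the wildtype lay on both sides. B2 is less clear over the 2 bins that HMRA1 overlaps, at 0.04 in its non-evolved and -0.37 in its evolved sample. Cells from outside the series and a common origin of both lines stay open and were not tested.

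The bin that holds HMRA2 of the silent mating-type cassette HMR (III 293001 to 294000) differed between the wildtype samples, with -1.08 evolved minus non-evolved and -0.77 evolved_Bub3 minus non-evolved. The largest difference between the states of a line was 0.417, in B2, which argues against counting and library noise. The wildtype samples may differ in mating type, but this cannot be told apart here: the bins of the alpha genes at MAT and HML differed by -0.0158, and they stood between -2.65 and -1.89 in all 46 samples, as reads shared by both copies would leave them. For that reason a small change there, named beforehand as evidence against this explanation, was not counted against it. A deletion or rearrangement at HMR was not tested.

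In the lines the same bin had 2 clusters of levels relative to III, with a gap between -0.30 and -0.07, and each of the 20 lines lay in the same cluster in both states. Below the gap, non-evolved and then evolved, it stood at -0.56 and -0.66 in A2, -0.59 and -1.0 in A3, -0.30 and -0.72 in B2, -0.68 and -0.84 in B3, and -0.49 and -0.56 in C1. It stood at -0.69 and -0.72 in C4, -0.75 and -0.55 in D2, -0.52 and -0.86 in D4, -0.78 and -0.73 in F3, and -0.71 and -0.67 in G1. Above the gap it stood at 0.06 and 0.22 in A1, 0.17 and 0.11 in A4, 0.13 and 0.20 in C2, 0.19 and -0.07 in C3, and 0.10 and 0.14 in D1. It stood at 0.10 and 0.11 in D3, -0.07 and 0.06 in E3, 0.11 and 0.14 in E4, 0.07 and 0.17 in F4, and 0.38 and 0.00 in G4. The wildtype stood at 0.21 in the non-evolved, -0.88 in the evolved and -0.56 in the evolved_Bub3 sample, on both sides of the gap. The evolved_Bub3 samples of C2, E3 and G4 stood at 0.03, 0.13 and 0.16. Over the 2 bins that HMRA1 overlaps, B2 stood at 0.04 in the non-evolved and -0.37 in the evolved sample. The other lines below the gap reached at most -0.24 there, in A2 non-evolved. By that measure B2 did not keep its cluster. No relation between these levels and other values was tested.

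The single bin that limma called between the states could be a chance result. When the states of random lines were swapped, 5 of 100 splits, the real one included, called as many bins, and the highest other split also called 1, so chance was not excluded.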
